A study of Homo sapiens with 14 samples.

How the data were processed

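RNA of Kasumi-1 cells (total RNA per the sample labels) was measured by RNA-seq in 10 libraries, in a knockdown experiment (shCtrl, n = 3, and shRBPMS, n = 3) and a treatment experiment (DMSO, n = 2, and RB98#, n = 2). The series lists 14 samples, and 4 of them, from RNA immunoprecipitation and m6A sequencing, were not analysed here. The labels do not say whether replicates are separate cultures, so the p-values may measure technical spread only.

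The submitters' processing notes name fastp 0.22.0, HISAT2 2.2.1, featureCounts 2.0.1, StringTie and DESeq2 1.32.0 on the genome build hg38/GRCh38, without saying which step each tool made. Each experiment has a table of Ensembl genes. Per the file headers and the whole numbers in them, the columns used here hold raw counts per gene and library, deposited without normalisation. The knockdown table held 16405 genes with a summed count of at least 27. The RB98# table held 12437 lines with a summed count of at least 50, and 12325 genes after 112 repeated lines were dropped by identifier. Both tables shared 12126 genes. The knockdown table also holds a signal column for each library, which the authors adjusted in a way the labels do not state. These signal values are whole numbers, within a tolerance of 0.05, divided by a factor per library. The whole numbers equal the counts in 1.94% to 3.90% of genes per library and differ from them in the rest. They were used as an alternative only. The log2 fold change and p-value columns come from the authors' own comparison, of the adjusted values in the knockdown table, and carry the header names of a DESeq2 table. The deposited log2 values and p-values are quoted where the text says so. A further 4 per-library columns were not used.

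Library totals were 24.03 to 34.38 M counts in the knockdown experiment and 13.9 to 15.3 M in the RB98# experiment. Levels are given as CPM (counts per 1e6 counts) scaled by TMM factors, as mean ± SD over the libraries of a group.

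The main tests were quasi-likelihood F tests of edgeR 4.0.16 on R 4.3.3, with TMM factors, the default filter of filterByExpr (a count of 10 and a total of 15), a design of group alone, and Benjamini-Hochberg adjustment at 0.05. They were two-sided. The SE of a log2 fold change is its size over the square root of F. Each experiment was fitted alone. The difference of both effects was tested as the contrast of (RB98# over DMSO) minus (shRBPMS over shCtrl) in a fit of all 10 libraries with 4 groups. The agreement of both experiments was tested across genes with Pearson's r and an exact permutation of the group labels within each experiment (repeated within the label sets and within same-numbered pairs after the data were seen), and the overlap of calls with Fisher's exact test. These tests, the 29 gene lists with 638 entries, of which 540 were found in a table, the rule for naming genes and most alternatives were chosen before the data were examined.

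In the knockdown experiment the library labels fall into 2 sets, set 1 with replicate 1 of each group and set 2 with replicates 2 and 3. What a set stands for is not stated. Whether same-numbered libraries share deviations was checked on log2 CPM after each group's mean was taken off, over 10606 genes. The correlation was 0.852, 0.772 and 0.800 for replicates 1, 2 and 3 of the knockdown experiment. Replicate 2 against replicate 3 gave 0.776 and 0.767, so the shared structure follows the label set, not the number. In the RB98# experiment the correlation was -0.0585. Knockdown results are given from the design of group alone and from a fit with the replicate number as a block, called the blocked fit. This block takes account of the label set, but these correlations give no basis for its pairing of numbers within set 2. The fit with the label set as a covariate, run as an alternative, called 5810 genes against 4549 in the blocked fit.

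Gene lists were tested with camera of limma 3.58.1 on the same fit, with its preset correlation between genes of 0.01, for lists with at least 5 tested members (27 lists in the knockdown, 26 with RB98#). The same test with an estimated correlation, and fry, were run as alternatives. The estimated test also lost calls in lists whose estimate lay below the preset 0.01, so a lost call alone does not show correlated members. For each list, members past 0.05 over all genes tested are counted, and members past 0.05 adjusted over the list alone.

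The named genes are RBPMS, USP1 and FOXO1. Added to them, per comparison, are the 6 genes per direction with the largest log2 fold change past 0.05, a mean log2 CPM of at least 2, a symbol, and no overlap between the groups. Each list gives up to 3 members past 0.05 with the largest change, without a minimum level. The agreement gives up to 6 genes per direction called in both experiments, and the difference up to 5 genes per sign, with the same minimum level. List members named from the blocked fit of the knockdown, and CEACAM6, were chosen after the values were seen.

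The fits were tested on simulated data with known folds, drawn around the mean level of each gene over both groups, kept apart by label set in the knockdown experiment, at the real library totals. The shares are of the changed genes that passed the filter. In the knockdown the fit without the block called 0% of genes changed by 1.5-fold, 3.23% at 2-fold and 58.1% at 4-fold, and the blocked fit called 77.3%, 91.9% and 100%. The RB98# fit called 82.1%, 91.0% and 97.0%. The test of the difference, with genes changed by RB98# only, called 0%, 0% and 62.1%. Genes simulated without a change gave 0 calls without the block, 7 with it, 9 for RB98# and 0 for the difference, out of 16041, 16041, 12324 and 12115 tested genes in these simulations. All libraries were drawn independently, with 1 dispersion for all genes and the same fold in both label sets. In the data replicates 2 and 3 of a group lay close, and RBPMS had a log2 ratio of -2.98 in set 1 and -1.17 in set 2. The simulation therefore cannot show how many false calls the fits make on the real libraries.

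Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals only, no count filter and a stricter one, the replicate block, the label set as a covariate, summed libraries, a fit of all 10 libraries, stricter thresholds and leaving out each library. Chosen after the data were seen were label set 2 alone, label set 1 alone for the agreement, summed libraries with the label set as a covariate, the authors' adjusted values, and list tests with the label set and on the difference. Gene positions, exon length and GC content came from GENCODE v29 on GRCh38. ComBat-seq was run from sva 3.50.0. Motif counts and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.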

Results

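RNA-seq counts were analysed from Kasumi-1, a leukemia cell line that carries the 8;21 translocation. In the knockdown experiment, cells took up a control shRNA (shCtrl, n = 3) or an shRNA against RBPMS (shRBPMS, n = 3) from a lentivirus for 48 h and were selected with puromycin for 48 h. In the treatment experiment, cells received DMSO (n = 2) or RB98# (n = 2), a compound known here only by its code name, at a dose and time that the labels do not give. Library totals were 24.03, 27.40 and 34.38 M counts (1 M is 1e6) for shCtrl and 25.2, 27.7 and 27.1 M for shRBPMS. They were 14.2 and 15.3 M for DMSO and 15.2 and 13.9 M for RB98#.

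Mitochondrially encoded genes took 15.2% of the counts in shCtrl replicate 1 and 13.2% in shRBPMS replicate 1. Their share was 6.28% and 6.20% in shCtrl replicates 2 and 3, and 6.95% and 6.76% in shRBPMS replicates 2 and 3. The library labels put replicate 1 of each group in one set (set 1) and replicates 2 and 3 in another (set 2). The first principal component, with 62.4% of the variance, parted these sets, and the second, with 32.03%, parted shCtrl from shRBPMS. Because both groups held libraries of both sets, the knockdown was fitted without a block and with the replicate number as a block, and the counts of each gene list are given for both. With RB98# the mitochondrial share was 8.39% and 8.17%, against 8.21% and 8.31% with DMSO, and the first component, with 84.5% of the variance, parted RB98# from DMSO.

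**Figure D1:**
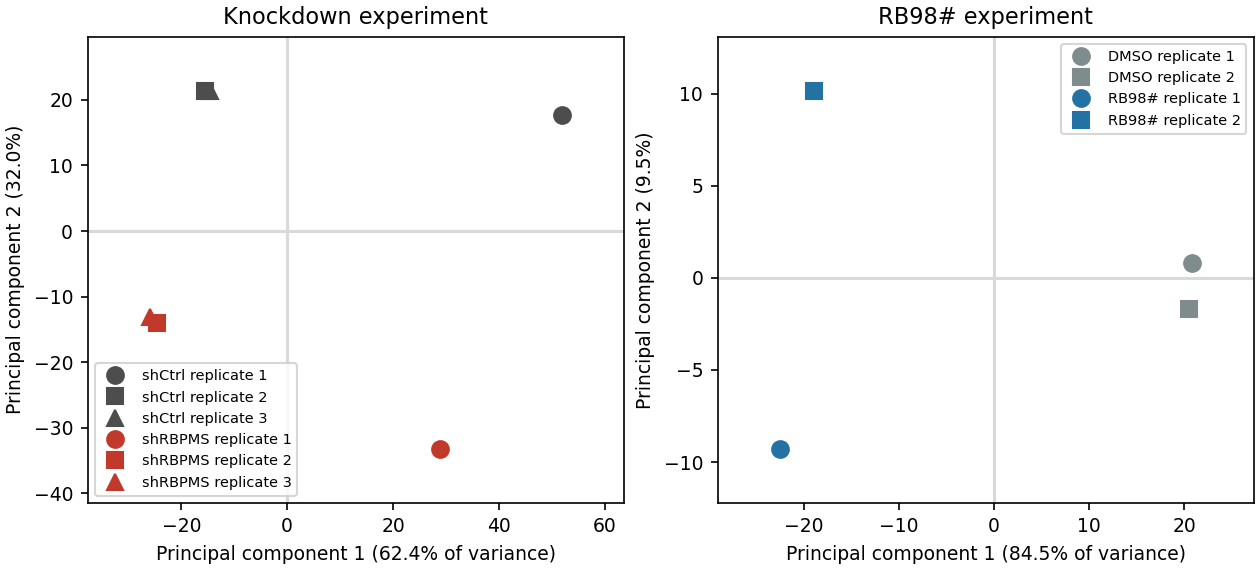
Principal components of log2 CPM, one point per library, with the knockdown experiment and the RB98# experiment in separate panels. In the knockdown, replicate 1 of shCtrl lies at 51.9 and of shRBPMS at 28.8 on the first component, and the other libraries lie between -14.6 and -26.0.

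The knockdown experiment asked what changes when RBPMS, which encodes an RNA-binding protein, is suppressed. The level of RBPMS was 11.7 ± 7.56 CPM (mean ± SD, n = 3) in shCtrl and 2.98 ± 0.413 CPM (n = 3) in shRBPMS, and every shRBPMS library lay below every shCtrl library. FOXO1, which encodes a forkhead transcription factor, was at 21.7 ± 14.7 CPM in shCtrl and 7.62 ± 0.384 CPM in shRBPMS. USP1, which encodes a deubiquitinase, was at 170 ± 3.66 CPM in shCtrl and 140 ± 9.21 CPM in shRBPMS. All of these fell in the blocked fit of edgeR, RBPMS with a log2 change of -1.79 (SE 0.35, adjusted p = 0.0106), FOXO1 with -1.32 (SE 0.28, adjusted p = 0.0137) and USP1 with -0.28 (adjusted p = 0.0176). Without the block none passed 0.05: the log2 change was -1.96 for RBPMS (SE 0.45, adjusted p = 0.0846), -1.51 for FOXO1 (SE 0.44, adjusted p = 0.145) and -0.28 for USP1 (SE 0.11, adjusted p = 0.259). Within set 1 the log2 ratio was -2.98 for RBPMS, -2.26 for FOXO1 and -0.40 for USP1, and within set 2 it was -1.17, -0.83 and -0.23. Without shCtrl replicate 1, which had 20.4 CPM of RBPMS against 7.24 and 7.39 CPM in the other shCtrl libraries, RBPMS passed without the block (-1.30, adjusted p = 0.0436), and FOXO1 had -0.81. With replicates 2 and 3 summed and the label set as a covariate, a fit chosen after the data were seen, RBPMS (-2.02) and FOXO1 (-1.52) passed and USP1 did not (-0.31, adjusted p = 0.117). In the authors' deposited table the log2 change of RBPMS was -1.53 (adjusted p = 1.18e-06), of FOXO1 -1.11 (adjusted p = 4.21e-05) and of USP1 -0.25 (adjusted p = 0.468).

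RBPMS (ENSG00000157110) lies on chromosome 8 from 30384479 to 30572261 on the plus strand of GRCh38. FOXO1 (ENSG00000150907) lies on chromosome 13 from 40469953 to 40666597 on the minus strand, and USP1 (ENSG00000162607) on chromosome 1 from 62436297 to 62451804 on the plus strand. All are protein-coding genes.

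**Figure D2:**
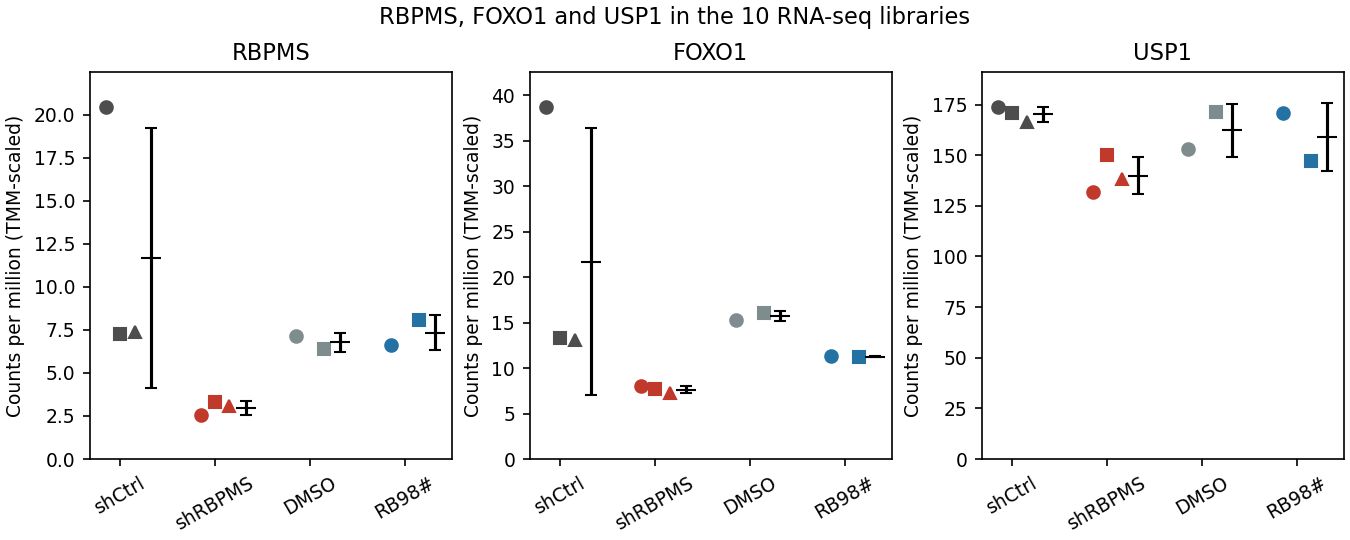
Level of RBPMS, USP1 and FOXO1 in TMM-scaled CPM, one point per library (circle, square and triangle for replicates 1, 2 and 3), with bars for mean ± SD. RBPMS was at 20.4, 7.24 and 7.39 CPM in the shCtrl libraries and at 2.53, 3.34 and 3.08 CPM in the shRBPMS libraries.

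Among genes with a mean log2 CPM of at least 2, the largest rises after the knockdown were those of SEMA4A, RAC2, HSD17B10, LAPTM5, PTPRC and RASAL3. PTPRC, which encodes the leukocyte phosphatase CD45, rose from 9.50 ± 0.412 to 46.4 ± 14.2 CPM (n = 3 each, log2 change 2.29, SE 0.23, adjusted p = 0.0222). RAC2, which encodes a GTPase of blood cells, rose from 14.8 ± 0.875 to 80.4 ± 28.4 CPM (2.44, SE 0.26), and LAPTM5, a lysosomal membrane protein of blood cells, from 7.52 ± 0.526 to 38.7 ± 18.8 CPM (2.36, SE 0.34). RASAL3, a Ras GTPase-activating protein, rose from 4.24 ± 0.342 to 19.3 ± 0.638 CPM (2.19, SE 0.15, adjusted p = 0.00879). SEMA4A, a semaphorin, rose from 2.09 to 12.7 CPM (2.60), and HSD17B10, a mitochondrial dehydrogenase, from 13.3 to 68.7 CPM (2.37). With DMSO, in the other experiment, RAC2 was at 55.5, HSD17B10 at 59.1 and LAPTM5 at 28.9 CPM. PTPRC was at 21.0, RASAL3 at 10.4 and SEMA4A at 3.20 CPM there. These rises are against shCtrl alone. The experiments were scaled apart, so the DMSO levels cannot show whether shCtrl or shRBPMS moved. The largest falls at that level were those of MT-TD, the mitochondrial tRNA for aspartate (log2 change -5.22, SE 0.77), SULT1C2, a sulfotransferase (-3.91, SE 0.46), and TRH, the precursor of thyrotropin-releasing hormone (-3.39, SE 0.51). They were followed by OLFML2A (-2.98), PPP1R16B, a regulatory subunit of protein phosphatase 1 (-2.72), and CCNJL (-2.54). Within set 1 the log2 ratio was -5.99 for MT-TD, -4.96 for SULT1C2 and -4.14 for OLFML2A, and within set 2 it was -4.08, -3.13 and -2.02. Without shCtrl replicate 1 the log2 change was -4.06 for MT-TD, -3.30 for SULT1C2, -2.81 for TRH and -2.20 for OLFML2A. TRH went from 166 ± 97.4 to 15.8 ± 7.54 CPM, and SULT1C2 from 38.6 ± 23.2 to 2.56 ± 0.452 CPM. Below that level CEACAM6, a cell adhesion molecule, had the largest rise of all (0.233 ± 0.141 to 26.5 ± 5.44 CPM, log2 change 6.79), and it was named after its values were seen. None of these genes but CEACAM6, which was not tried singly, was called without shCtrl replicate 2 or 3 or shRBPMS replicate 2 or 3. Without shRBPMS replicate 1 the calls of HSD17B10 (2.59) and of all 6 falls were lost, and LAPTM5 was not called without shCtrl replicate 1 (2.40).

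Of 16215 genes tested with edgeR without the block, 102 rose and 218 fell (1.97% of those tested). The blocked fit called 2157 genes up and 2392 down (28.1%), among them all 320 of the fit without the block, in the same direction. Replicates 2 and 3 of a group lay closer than other pairs of its libraries (chi-square per degree of freedom 3.01 in shCtrl and 3.03 in shRBPMS, against 194 for shCtrl replicates 1 and 2), and the labels do not say whether they are separate cultures. With replicates 2 and 3 summed, edgeR called 0 genes (1086 at an unadjusted p under 0.05), and 2681 with the label set as a covariate, a fit chosen after the data were seen. The list counts of the blocked fit below also take replicates 2 and 3 as separate. In 4200 genes (25.9%) the libraries of both groups did not overlap, where chance gives 10% if all libraries are independent and exchangeable. The closeness of replicates 2 and 3 and the label sets go against that, so the chance share may be higher than 10%. At an adjusted p under 0.05 the authors' deposited table holds 778 genes up and 1083 down. Without the block the count was 2 without shCtrl replicate 2, 0 without shCtrl replicate 3 (2010 at an unadjusted p under 0.05), 37 without shRBPMS replicate 1, 0 without shRBPMS replicate 2 (1866) and 0 without shRBPMS replicate 3 (2002), all in edgeR. MT-TD and OLFML2A were not called by limma-voom.

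Genes of DNA replication and mitosis were lower after the knockdown as groups. Of 35 genes of DNA replication 34 had a lower mean (median log2 change -0.38, camera adjusted p = 2.6e-07, but adjusted p = 0.324 with an estimated correlation), and in the blocked fit 31 fell and 0 rose. MCM6, a subunit of the replicative helicase, went from 302 ± 17.2 to 205 ± 11.6 CPM (blocked log2 change -0.56, adjusted p = 0.00108), and MCM4 from 478 to 325 CPM (-0.56). All 28 genes of G2 and mitosis had a lower mean (median -0.27, camera adjusted p = 0.00206, but adjusted p = 0.605 with an estimated correlation), and 17 fell and 0 rose in the blocked fit. FOXM1, a transcription factor of the cell cycle, went from 144 to 79.8 CPM (blocked log2 change -0.83, adjusted p = 0.000933), and CCNA2, cyclin A2, had -0.44. Of 9 genes in the list of USP1 with its partners and substrates, 7 fell and 0 rose in the blocked fit. USP1 itself is among the 7, and PCNA is also in the DNA replication list. The list median without the block was -0.45 (camera adjusted p = 0.00266, but adjusted p = 0.324 with an estimated correlation). FANCD2, a DNA repair protein that USP1 deubiquitinates, went from 140 ± 5.89 to 93.9 ± 2.67 CPM (blocked log2 change -0.57, adjusted p = 0.00119), and ID3 had -2.03. Without the block 0 members of these lists passed over all genes, and 4 genes of DNA replication, 0 of G2 and mitosis and 5 USP1 partners were lower when adjusted over the list alone. The members named here were chosen after their values were seen.

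Interferon response genes were lower as a group (26 tested, median log2 change -0.52, camera adjusted p = 0.00266, but adjusted p = 0.324 with an estimated correlation). DDX60 fell by 1.23 on the log2 scale, from 14.9 to 6.33 CPM, and HERC5 fell by 0.81. These 2 were also the members that passed when adjusted over the list alone, and the blocked fit called 10 down and 1 up. Of 7 lymphoid markers 2 fell, CD3D (-1.91, 8.46 to 2.24 CPM) and CD3E (-3.08, 1.31 to 0.151 CPM), over all genes and adjusted over the list alone (median -0.15, camera adjusted p = 0.0185, but adjusted p = 0.324 with an estimated correlation), and the blocked fit called 3 down and 0 up. Of 5 megakaryocyte and platelet markers 2 fell on both counts, over all genes and adjusted over the list alone. Among them was ITGA2B, a platelet integrin (-1.72), with a list median of -0.07 and camera adjusted p = 0.0354, but adjusted p = 0.324 with an estimated correlation. The platelet list was not called in the blocked fit (adjusted p = 0.0977, 2 down and 0 up) or without shRBPMS replicate 1 (adjusted p = 0.0664). With the label set as a covariate neither the lymphoid list (adjusted p = 0.0659) nor the platelet list (0.101) was called, as in label set 2 alone (0.0670 and 0.149) and with summed libraries and the label set (0.0622 and 0.0595). Of the genes named in this paragraph none was called without shCtrl replicate 2 or 3 or shRBPMS replicate 2 or 3, where edgeR called 2, 0, 0 and 0 genes in all (2073, 2010, 1866 and 2002 at an unadjusted p under 0.05). Without shRBPMS replicate 1 CD3D alone of these genes was called.

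Monocyte and macrophage markers were higher as a group (10 of 22 listed were tested, median log2 change 0.63, camera adjusted p = 0.0151, but adjusted p = 0.324 with an estimated correlation and adjusted p = 0.0542 in the blocked fit). None passed over all genes without the block, and 3 up and 1 down passed adjusted over the list alone. In the blocked fit 5 rose and 1 fell. The largest rises were at low levels, TYROBP from 0.282 to 0.840 CPM and CSF1R from 0.349 to 0.979 CPM. MNDA had 1.17 and CTSS, a lysosomal protease, 1.06. FCGR2A was lower in the authors' deposited table (-0.79). All of these were named after their values were seen. Of 12 replication-dependent histone genes 4 rose and 1 fell in the blocked fit, with low levels such as 1.05 and 4.38 CPM for H2AC6 (blocked log2 change 2.10), also named after its values were seen. The histone list had a median of 0.80 (camera adjusted p = 0.0118, but adjusted p = 0.324 with an estimated correlation), with 0 members called over all genes and 4 up and 1 down adjusted over the list alone. Cytosolic ribosomal proteins had a median of 0.18 over 44 genes (camera adjusted p = 0.0411, but adjusted p = 0.882 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. This call was lost without shCtrl replicate 1, where the direction changed without a call (adjusted p = 0.955), and without shRBPMS replicate 2 (0.338) or 3 (0.343), and the blocked fit called 19 members up and 0 down. With the label set as a covariate the monocyte list (adjusted p = 0.0855) and the histone list (0.0525) were not called, nor in label set 2 alone (0.0670 and 0.149). The ribosomal protein list was lower in set 1 than in set 2 by a median log2 ratio of -0.85 in shCtrl and -0.67 in shRBPMS.

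Myeloid and leukemia genes moved both ways. SPI1, which encodes the myeloid transcription factor PU.1, rose from 41.3 ± 8.35 to 117 ± 4.56 CPM (log2 change 1.498, SE 0.18, adjusted p = 0.0233), while TRH fell, in a list of 15 genes of the t(8;21) fusion. That list was not called without the block (median -0.32, adjusted p = 0.119; 1 up and 3 down adjusted over the list alone), and was lower in the blocked fit (adjusted p = 0.00123, but adjusted p = 0.502 with an estimated correlation), with 2 up and 8 down. Of 19 stem and progenitor genes SOCS2 rose (0.91) and CPXM1 fell (-1.46, 69.5 ± 9.08 to 25.2 ± 3.19 CPM), with 2 up and 6 down adjusted over the list alone (median -0.08, adjusted p = 0.0709, and in the blocked fit 0.0402 with 3 up and 7 down, but adjusted p = 0.502 with an estimated correlation). Of 12 neutrophil granule genes BPI, a bactericidal protein, rose from 1.87 ± 0.578 to 6.58 ± 1.17 CPM (1.81), with 2 up and 1 down adjusted over the list alone, and 3 up and 2 down in the blocked fit. The neutrophil list had a median of -0.02, a mean of 0.26 and a test in the upward direction (adjusted p = 0.567). In the m6A machinery (20 tested) IGF2BP3, an m6A reader, fell from 74.7 ± 16.1 to 26.4 ± 2.11 CPM (adjusted p = 0.0258), the 1 member called over all genes and adjusted over the list alone (list median -0.14, adjusted p = 0.263), while the blocked fit called 3 members up and 5 down. SOCS2 was not called with library totals only. None of the genes named here was called without shCtrl replicate 2 or 3 or shRBPMS replicate 2 or 3, where edgeR called 2, 0, 0 and 0 genes (2073, 2010, 1866 and 2002 at an unadjusted p under 0.05), and without shRBPMS replicate 1 only CPXM1 was.

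Targets of FOXO factors were not called as a list (23 tested, median log2 change -0.18, adjusted p = 0.186). None passed over all genes without the block, 1 up and 4 down passed adjusted over the list alone, and the blocked fit called 3 up and 7 down. The p53 targets held 1 rise of 21, RRM2B, a ribonucleotide reductase subunit (1.04), over all genes and adjusted over the list alone (median -0.20, adjusted p = 0.654), with 2 up and 3 down in the blocked fit. In the BCL2 family (14 tested) BMF fell (-1.62), with 1 up and 5 down adjusted over the list alone (median -0.28, adjusted p = 0.0933) and 3 up and 7 down in the blocked fit. SLC2A3, a glucose transporter, fell from 193 ± 84.9 to 48.0 ± 9.33 CPM (-2.003), the 1 call among 21 genes of hypoxia and glycolysis on both counts, over all genes and adjusted over the list alone (median -0.13, adjusted p = 0.228), with 1 up and 6 down in the blocked fit. Among 13 NF-kB and inflammatory genes NFKBIA, an inhibitor of NF-kB, fell from 34.6 to 18.2 CPM (-0.92) and TNF fell from 1.35 to 0.1004 CPM (-3.71), with 1 up and 4 down adjusted over the list alone, whereas the blocked fit called 6 up and 4 down. That list had a median of 0.27, a mean of -0.23 and a test in the downward direction (adjusted p = 0.438). TNF and NFKBIA were not called by limma-voom. The genes called here were not called without shCtrl replicate 2 or 3 or shRBPMS replicate 2 or 3 (2, 0, 0 and 0 genes in edgeR, and 2073, 2010, 1866 and 2002 at an unadjusted p under 0.05) or without shRBPMS replicate 1. BMF (-1.40) and TNF (-3.79) also lost the call without shCtrl replicate 1, and TNF lay at -3.11 and -4.47 without shRBPMS replicates 2 and 3.

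The other lists had 0 members called over all genes in edgeR without the block. Nuclear OXPHOS subunits (42 tested, median log2 change 0.11, adjusted p = 0.227), mitochondrially encoded mRNAs (13 tested, median 0.02, mean -0.06, test upward, adjusted p = 0.870) and heat shock genes (16 tested, median 0.11, adjusted p = 0.846) had 0 adjusted over the list alone. So had cholesterol synthesis (23 tested, median -0.03, mean 0.05, test downward, adjusted p = 0.846), NRF2 targets (18 tested, median 0.21, adjusted p = 0.0933) and ER chaperones (18 tested, median 0.03, adjusted p = 0.846). ATF4 targets had 1 up adjusted over the list alone (22 tested, median 0.00, mean -0.02, test upward, adjusted p = 0.834). Ribosome biogenesis and MYC targets had 1 down adjusted over the list alone (26 tested, median 0.08, adjusted p = 0.567), as had AP-1 and immediate early genes (20 tested, median -0.25, adjusted p = 0.846). Of 2 erythroid markers 1 was lower adjusted over the list alone (median -0.46), and of 2 stromal and epithelial markers 0 were called (median 0.10), both lists too small for the test. The blocked fit called 11 OXPHOS subunits up and 3 down, 6 NRF2 targets up and 1 down, 6 ribosome biogenesis and MYC targets up and 2 down, 2 ATF4 targets up and 4 down, and 3 AP-1 and immediate early genes up and 4 down. It called 2 cholesterol synthesis genes up and 2 down, 1 up and 1 down among heat shock genes and among ER chaperones, 1 mitochondrially encoded mRNA down, 1 erythroid marker down and 1 stromal or epithelial marker up.

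RB98# was compared with DMSO to see which genes the compound changes in the same cells. JUN, a subunit of the transcription factor AP-1, rose from 13.98 ± 0.553 to 213 ± 4.21 CPM (n = 2 each, log2 change 3.93, SE 0.08, adjusted p = 2.14e-21). DUSP8, a MAP kinase phosphatase, rose from 0.954 ± 0.196 to 37.4 ± 2.37 CPM (5.29, SE 0.19, adjusted p = 6.6e-17), and FHL2 from 1.15 ± 0.949 to 26.9 ± 1.68 CPM (4.51, SE 0.24). THBS1, which encodes thrombospondin 1, rose from 4.89 ± 0.448 to 55.2 ± 1.93 CPM (3.49), GLIPR1 from 14.5 ± 2.97 to 155 ± 20.7 CPM (3.41) and IQCN by a log2 change of 3.73. HPDL fell from 40.9 ± 0.592 to 9.80 ± 0.337 CPM (-2.06, SE 0.12, adjusted p = 5.37e-13), and POLR1G, a subunit of RNA polymerase I, from 28.6 ± 1.48 to 9.28 ± 1.24 CPM (-1.63, SE 0.13). TFAP4, a transcription factor, fell from 28.7 to 9.47 CPM (-1.60), MAP6D1 by a log2 change of -1.66, JMJD4 of -1.57 and EMSLR of -1.54. FHL2 had a log2 change of 3.88 without DMSO replicate 1 and 5.79 without DMSO replicate 2, and MAP6D1 of -2.33 without RB98# replicate 1 and -1.24 without RB98# replicate 2. All of these were called without each library in turn, and HPDL, MAP6D1, JMJD4 and EMSLR were not called in a fit of all 10 libraries of both experiments.

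FOXO1 fell with RB98# from 15.7 ± 0.544 to 11.3 ± 0.0929 CPM (n = 2 each, log2 change -0.48, SE 0.14, adjusted p = 0.00814). That call was lost without DMSO replicate 2 (-0.44, adjusted p = 0.0958) and in DESeq2 (adjusted p = 0.0584). RBPMS was at 6.78 ± 0.544 CPM with DMSO and 7.34 ± 1.02 CPM with RB98# (0.11, SE 0.19, adjusted p = 0.678). USP1 was at 162 ± 12.97 and 159 ± 16.9 CPM (-0.03, SE 0.07, adjusted p = 0.785), but it passed without RB98# replicate 1 (-0.16, adjusted p = 0.0478). The authors' deposited table gives FOXO1 a log2 change of -0.47 (adjusted p = 0.129), RBPMS 0.12 (0.862) and USP1 -0.03 (0.896).

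Of 12324 genes tested with edgeR 2530 rose and 2129 fell with RB98# (37.8%). The groups did not overlap in 8418 genes (68.3%), where chance gives 33.3% if all libraries are independent cultures. The count was 2843 without DMSO replicate 1 and 2731 without DMSO replicate 2. Scaled by library totals only, the median of all genes moved to -0.10 and the share of rises among the calls went from 54.3% to 34.03% (1690 up and 3276 down). Of the named genes with RB98#, 84 kept their result with library totals only and 11 lost the call. The genes that kept their result include RBPMS, which was uncalled in every fit. In a fit of all 10 libraries 352 genes were called with RB98#, and of the named genes 30, again with RBPMS, kept their result and 64 lost the call. At an adjusted p under 0.05 the authors' deposited table holds 1693 genes up and 1040 down. The libraries of a group lay close, with a chi-square per degree of freedom of 2.24 for DMSO and 4.90 for RB98#. Whether they are separate cultures is not stated in the labels. Label set 2 alone, a knockdown fit of similarly close libraries chosen after the data were seen, called 6830 genes. The RB98# count therefore cannot be set against the 320 knockdown genes without the block as a measure of effect size.

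Cholesterol synthesis genes rose with RB98#: 21 of 23 rose and 0 fell over all genes, and 21 were up and 1 down adjusted over the list alone (median log2 change 0.72, camera adjusted p = 3.7e-34, but adjusted p = 0.157 with an estimated correlation). INSIG1, a regulator of sterol synthesis, rose from 195 ± 8.44 to 623 ± 44.3 CPM (1.68), and MSMO1, a sterol oxidase, from 39.9 to 120 CPM (1.59). ATF4 targets rose in 19 of 22, over all genes and adjusted over the list alone (median 0.63, camera adjusted p = 1.7e-25, but adjusted p = 0.344 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 7.68 ± 2.45 to 65.3 ± 5.95 CPM (3.08), CHAC1 from 1.56 to 13.1 CPM (3.06) and DDIT4, an inhibitor of mTORC1 signalling, from 48.3 to 211 CPM (2.13). AP-1 and immediate early genes had 12 rises and 4 falls of 19 on both counts, over all genes and adjusted over the list alone (median 0.66, camera adjusted p = 2.6e-09, but adjusted p = 0.255 with an estimated correlation). JUND rose from 32.8 to 190 CPM (2.53), and DUSP5, a MAP kinase phosphatase, from 4.07 to 13.6 CPM (1.74).

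Ribosome biogenesis and MYC targets fell in 19 of 26 genes and rose in 0, over all genes and adjusted over the list alone (median log2 change -0.37, camera adjusted p = 1.2e-10, but adjusted p = 0.222 with an estimated correlation). RRS1 fell from 64.2 to 25.8 CPM (-1.32), POLR1B, a subunit of RNA polymerase I, from 138 to 70.2 CPM (-0.98), and NOP16 from 70.2 to 36.6 CPM (-0.94). DNA replication genes had 16 falls and 1 rise of 35, and 17 and 1 adjusted over the list alone, or 10 and 1 over all genes with the replicate number as a block (median -0.16, camera adjusted p = 0.00111, but adjusted p = 0.367 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 260 ± 10.8 to 126 ± 0.202 CPM (-1.05), CCNE1, cyclin E1, from 33.2 to 20.53 CPM (-0.69), and E2F1 was the 1 rise (0.54). G2 and mitosis genes had 4 rises, such as HMMR (0.42), and 2 falls of 28, and 4 and 1 adjusted over the list alone (median -0.01, mean 0.02, test downward, adjusted p = 0.961).

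Targets of FOXO factors rose in 14 and fell in 3 of 23 genes, over all genes and adjusted over the list alone (median log2 change 0.36, camera adjusted p = 5.8e-05, but adjusted p = 0.417 with an estimated correlation). KLF2, a transcription factor, rose from 3.44 to 15.6 CPM (2.18), and CDKN1A, the cyclin-dependent kinase inhibitor p21, from 9.35 ± 0.0961 to 37.1 ± 4.41 CPM (1.99). The p53 targets had 11 rises and 2 falls of 21 on both counts, over all genes and adjusted over the list alone (median 0.34, camera adjusted p = 0.00128, but adjusted p = 0.367 with an estimated correlation). BTG2 rose by a log2 change of 2.42 and SESN2, a stress-induced sestrin, from 13.3 to 56.1 CPM (2.07). In the BCL2 family 5 rose and 2 fell of 14, also adjusted over the list alone (median 0.08, camera adjusted p = 0.00879, but adjusted p = 0.367 with an estimated correlation). PMAIP1, the pro-apoptotic protein NOXA, rose from 28.9 ± 0.958 to 163 ± 24.4 CPM (2.50), and MCL1, an anti-apoptotic protein, from 264 to 486 CPM (0.88). BBC3, a member of the FOXO, p53 and BCL2 lists, rose by a log2 change of 1.78, a call lost without DMSO replicate 2 (1.097) and kept without DMSO replicate 1 (3.003). CDKN1A is also in the p53 list, and SESN2 in the ATF4 list, so the rises of these lists are not separate findings.

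NRF2 targets rose in 8 and fell in 1 of 17 genes, over all genes and adjusted over the list alone (median log2 change 0.20, camera adjusted p = 0.00879, but adjusted p = 0.533 with an estimated correlation). SLC7A11, a cystine transporter that is also in the ATF4 list, rose from 17.4 ± 0.212 to 60.4 ± 8.37 CPM (1.80), and FTH1, ferritin heavy chain, from 195 to 293 CPM (0.59). NF-kB and inflammatory genes had 5 rises and 1 fall of 12, also adjusted over the list alone (median 0.21, camera adjusted p = 0.0411, but adjusted p = 0.410 with an estimated correlation), and the list was not called without RB98# replicate 2 (adjusted p = 0.0733). CXCL8, interleukin 8, rose from 7.92 ± 0.103 to 29.7 ± 9.32 CPM (1.91), RELB by a log2 change of 1.41 and TNFAIP3 by 1.40. Hypoxia and glycolysis genes had 7 rises, among them SLC2A3 (0.95) and KDM3A (0.97), and 1 fall of 20, and 7 and 2 adjusted over the list alone (median 0.09, adjusted p = 0.0580).

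Lineage lists were not called with RB98#. Of 17 stem and progenitor genes 3 rose and 4 fell, also adjusted over the list alone (median log2 change -0.02, adjusted p = 0.187). TAL1, a transcription factor of blood stem cells, fell from 74.6 ± 1.97 to 31.8 ± 4.34 CPM (-1.23), and ARHGAP22 by a log2 change of -1.17. Of 15 genes of the t(8;21) fusion 6 rose and 3 fell, also adjusted over the list alone (median 0.20, adjusted p = 0.335), and CEBPA, a myeloid transcription factor, fell from 23.9 to 13.6 CPM (-0.81). Monocyte markers had 2 rises, FCGR1A (1.07) and FCGR2A (0.86), and 1 fall of 10, and 2 and 0 adjusted over the list alone (median 0.34, adjusted p = 0.217). Neutrophil granule genes had 6 rises, among them SRGN (0.39), and 0 falls of 11, also adjusted over the list alone (median 0.18, adjusted p = 0.217). Lymphoid markers had 0 calls of 5, also adjusted over the list alone (median 0.01, mean 0.07, test downward, adjusted p = 0.961). The lists of 2 erythroid, 3 megakaryocyte and 1 stromal or epithelial markers were too small for the test, with medians of -0.55, -0.22 and -0.21. Of these the erythroid list had 1 fall over all genes, KLF1 (-1.30), which was not called without DMSO replicate 1 (-1.39), DMSO replicate 2 (-1.19), RB98# replicate 1 (-1.39) or RB98# replicate 2 (-1.22). Adjusted over the list alone 1 erythroid, 0 megakaryocyte and 1 stromal or epithelial marker were lower.

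Cytosolic ribosomal proteins had 12 rises and 0 falls of 44, and 7 and 0 adjusted over the list alone (median log2 change 0.11, adjusted p = 0.0565), but with the replicate number as a block 3 rises over all genes and 0 over the list alone. RPL5 rose by a log2 change of 0.22, a call lost with library totals only (0.12), without DMSO replicate 1 (0.23) and without DMSO replicate 2 (0.22). Mitochondrially encoded mRNAs had 7 rises, among them MT-ND4 (0.25), and 3 falls of 13, also adjusted over the list alone (median 0.12, adjusted p = 0.639), and 4 rises and 3 falls with the block. OXPHOS subunits had 2 rises and 2 falls of 42, and 1 and 2 adjusted over the list alone (median 0.03, mean 0.02, test downward, adjusted p = 0.961). Heat shock genes had 4 falls, among them HSPA1B (-0.33), and 0 rises of 16, also adjusted over the list alone (median -0.11, adjusted p = 0.149). ER chaperones had 5 rises, among them HERPUD1 (0.67) and EDEM1 (0.47), and 2 falls of 18, also adjusted over the list alone (median 0.06, adjusted p = 0.579). Interferon response genes had 3 rises, among them IRF7 (1.05), and 4 falls of 23, and 1 and 4 adjusted over the list alone (median -0.18, adjusted p = 0.513). The m6A machinery had 5 rises, among them RBM15 (29.5 to 47.3 CPM, 0.68), and 2 falls of 20, also adjusted over the list alone (median 0.03, adjusted p = 0.597). The list of USP1 with its partners had 2 rises and 3 falls of 9, also adjusted over the list alone, and USP1 itself was not called. The list median was -0.03 and the mean 0.01 (test downward, adjusted p = 0.632). With the block 2 members rose and 1 fell. ID1 fell from 39.0 to 23.0 CPM (-0.76). Histone genes had 0 calls of 6 in edgeR, also adjusted over the list alone (median 0.03, mean -0.01, test downward, adjusted p = 0.958). HSPA1B was not called by DESeq2 (-0.34, adjusted p = 0.0792), but in the authors' deposited table it was past 0.05 (-0.33, adjusted p = 0.000946).

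**Figure D3:**
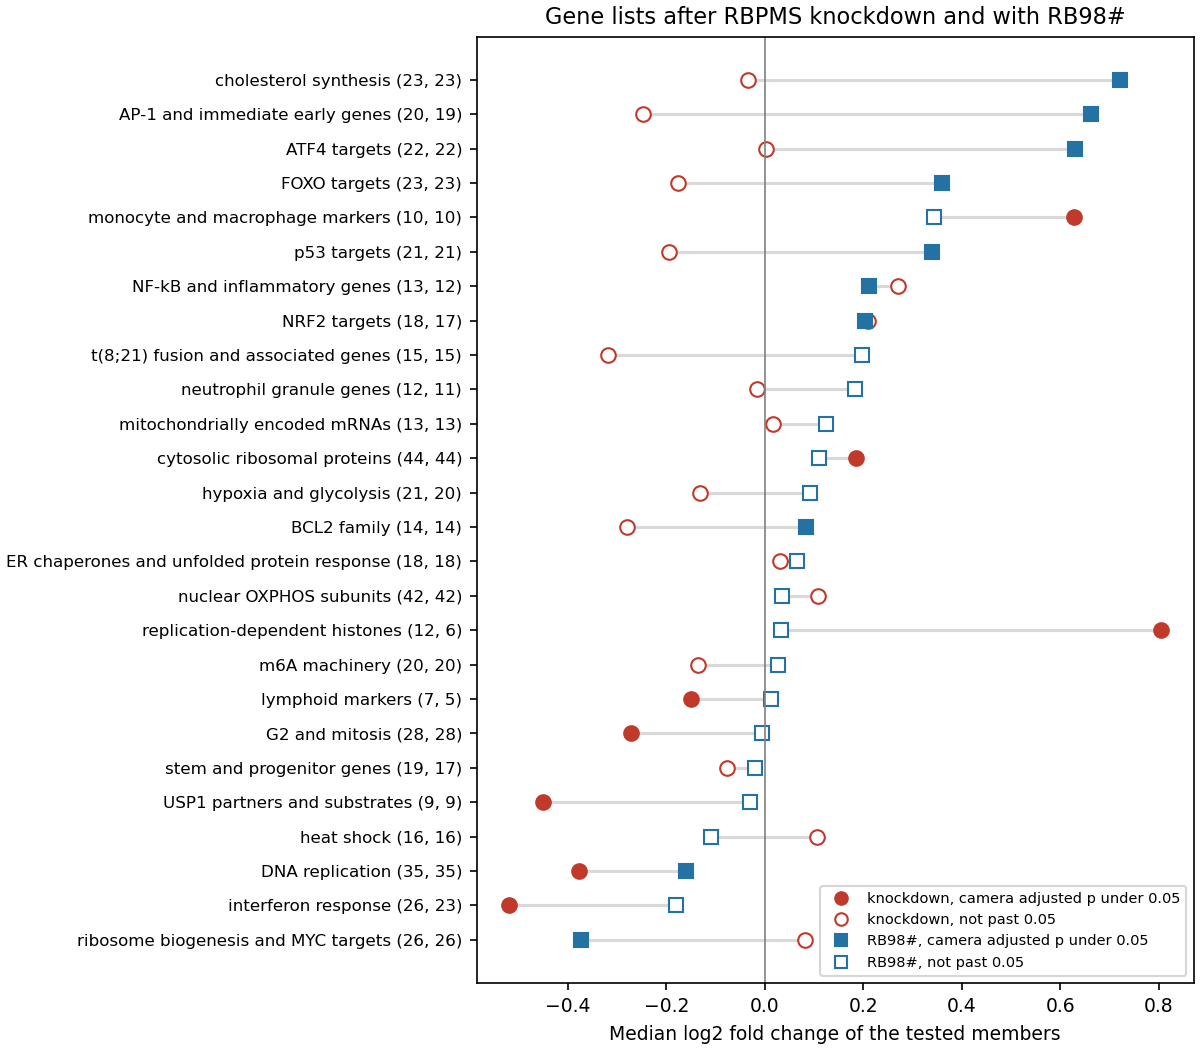
Median log2 change of each gene list tested in both comparisons, with circles for the knockdown and squares for RB98#, filled where the camera adjusted p was under 0.05, and the numbers of tested members in brackets. Cholesterol synthesis lies at -0.03 in the knockdown and 0.72 with RB98#, and DNA replication at -0.38 and -0.16; the ribosomal protein call of the knockdown was lost without shCtrl replicate 1 (adjusted p = 0.955).

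The changes after RBPMS knockdown and with RB98# were compared gene by gene to see whether they point the same way. PTPRC rose in both experiments (log2 change 2.29 after the knockdown and 0.75 with RB98#), as did CR1, a complement receptor (2.03 and 0.68), and DHRS9 (1.77 and 0.57). TUBB4A, a tubulin, fell in both (-2.05 and -1.31), as did PRTG (-1.86 and -0.83), PPP1R18 (-1.70 and -0.50), TRIM47 (-1.09 and -1.24) and LHFPL2 (-0.95 and -1.07). LAPTM5 rose in both (2.36 and 0.31), but its call with RB98# was lost without DMSO replicate 1 (0.29), DMSO replicate 2 (0.32) or RB98# replicate 2 (0.20). Such shared calls were no more frequent than chance gives without the block: 19 genes rose in both against 19.8 by chance, and 26 fell in both against 33.4 (Fisher's exact test, adjusted p = 0.929 and 0.357). Nor were calls in opposite directions, with 40 genes that fell after the knockdown and rose with RB98# against 39.7 (adjusted p = 0.929) and 19 the other way against 16.7 (0.802). With the blocked knockdown 561 genes fell after the knockdown and rose with RB98# against 451 by chance (adjusted p = 3.2e-09), and 410 rose after the knockdown and fell with RB98# against 344 (0.000113). In the same fit 324 fell in both against 380 (0.00113) and 400 rose in both against 409 (0.808). Fisher's test takes genes as independent, which they are not, so its p-values do not measure the spread between libraries. Across 12115 genes, which are not independent replicates, Pearson's r was -0.08 and Spearman's rho -0.11, and 47.0% of genes had the same sign. The exact permutation p, two-sided over 30 combinations of group labels, was 0.5, where 0.0333 is the smallest it can be. With labels exchanged only within the label sets, which was chosen after the data were seen, 5 of 18 combinations were as large (exact permutation p = 0.278, with 0.0556 as the smallest). Exchanged within same-numbered pairs, also chosen afterwards, 3 of 12 were as large (exact permutation p = 0.25, with 0.0833 as the smallest). Within label set 1 r was -0.13, within label set 2 it was -0.04, and without shCtrl replicate 1 it was -0.02. The knockdown calls named here were not called without shCtrl replicate 2 or 3 or shRBPMS replicate 2 or 3, where edgeR called 2, 0, 0 and 0 genes (2073, 2010, 1866 and 2002 at an unadjusted p under 0.05). Without shRBPMS replicate 1 those of PTPRC, CR1 and LAPTM5 held, and without shCtrl replicate 1 those of LAPTM5 (2.40), TRIM47 (-1.11) and LHFPL2 (-0.85) were lost.

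The difference of both effects was tested directly, as the log2 change with RB98# minus that after the knockdown. CDKN1C, the cyclin-dependent kinase inhibitor p57, fell after the knockdown from 7.87 ± 1.503 to 0.372 ± 0.0493 CPM (n = 3 each) and was at 3.85 CPM with DMSO and 5.04 CPM with RB98# (n = 2 each), a difference of 4.75 (SE 0.39, adjusted p = 0.00163). PPP1R16B fell after the knockdown and rose with RB98# from 10.8 to 36.0 CPM, a difference of 4.44 (SE 0.50, adjusted p = 0.00392). DUSP8 differed by 4.12 (SE 0.39, adjusted p = 0.00248). CD33, a myeloid surface receptor, rose after the knockdown from 15.3 to 50.0 CPM (1.71) and fell with RB98# from 24.4 to 13.7 CPM (-0.84), a difference of -2.56 (SE 0.29, adjusted p = 0.00392). RAC2 (-2.87) and TRDC (-2.70) differed in the same direction as CD33. RBPMS (2.06, adjusted p = 0.0824), FOXO1 (1.01, adjusted p = 0.362) and USP1 (0.24, adjusted p = 0.423) did not pass, and with the block RBPMS did (adjusted p = 0.0182).

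JUN (4.59, SE 0.97) and FHL2 (4.36, SE 0.75) were higher with RB98# by the same test, and HSD17B10 (-2.51, SE 0.45) and TBC1D10C (-2.81, SE 0.65) lower. JUN lay between 3.82 and 5.20 with a library left out, and FHL2 between 3.72 and 5.64. JUN lost the call without shRBPMS replicate 3 (4.44), DMSO replicate 1 (4.55) or 2 (4.63), or RB98# replicate 1 (4.56) or 2 (4.61). FHL2 lost it without DMSO replicate 1 (3.72) and RB98# replicate 1 (4.29) or 2 (4.43), and HSD17B10 without DMSO replicate 1 (-2.57) or 2 (-2.46) and RB98# replicate 1 (-2.39) or 2 (-2.65). TBC1D10C lost it without shRBPMS replicate 2 (-2.72) or 3 (-2.69), DMSO replicate 1 (-2.93) or 2 (-2.69), and RB98# replicate 1 (-2.77) or 2 (-2.87).

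Of 12126 genes 581 were higher with RB98# than after the knockdown and 407 lower (8.15%), and with the replicate block 2290 and 2207. The total of 988 went to 1541 without shCtrl replicate 1, 646 without shCtrl replicate 2, 589 without shCtrl replicate 3, 434 without shRBPMS replicate 2 and 457 without shRBPMS replicate 3. It went to 100 and 92 without DMSO replicates 1 and 2, and to 132 and 222 without RB98# replicates 1 and 2. Among genes that differed with the block, 971 had calls in opposite directions, 410 up and 561 down after the knockdown. These counts equal those of the blocked overlap, where chance gave 344 and 451, so they are not a separate finding. Cholesterol synthesis (median difference 0.67, camera adjusted p = 4.8e-05), ATF4 targets (0.62, adjusted p = 8.2e-05), FOXO targets (0.62, adjusted p = 0.00701), p53 targets (0.54, adjusted p = 0.00701) and the BCL2 family (0.17, adjusted p = 0.0281) were higher with RB98#, and ribosome biogenesis and MYC targets lower (-0.40, adjusted p = 0.000508). These became adjusted p = 0.485, 0.485, 0.485, 0.385, 0.588 and 0.485 with an estimated correlation, in that order, and this list test was chosen after the data were seen. With the block, camera also called AP-1 and immediate early genes (adjusted p = 0.000409), G2 and mitosis (0.00849) and the t(8;21) list (0.00849) higher with RB98#. Without the block these had 0.129, 0.0625 and 0.239, and with the block and an estimated correlation 0.571, 0.662 and 0.505.

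**Figure D4:**
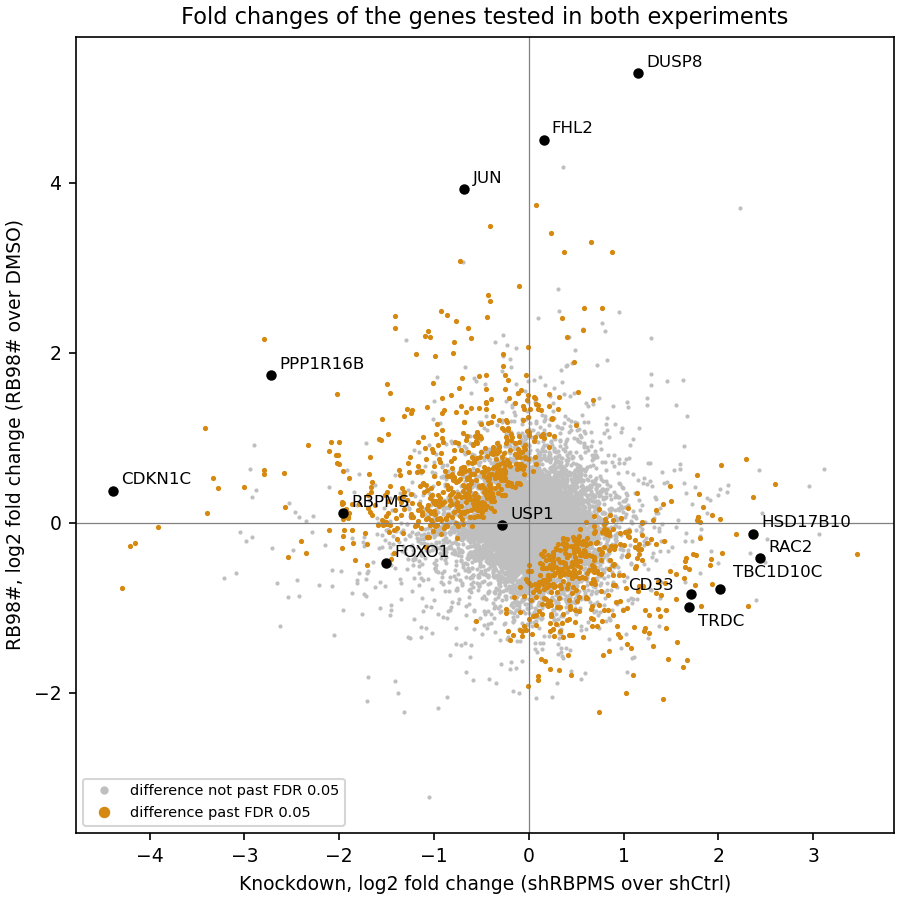
Log2 change after RBPMS knockdown (horizontal) against log2 change with RB98# (vertical), one point per gene tested in both, in orange where the difference passed an adjusted p of 0.05, with named genes in black. CD33 lies at 1.71 and -0.84, and PPP1R16B at -2.72 and 1.74.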

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

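The test of the difference was planned. Chosen after the results were seen were the tests of the label sets as a mask and of noise for the agreement, of its permutation within the label sets, of length and GC content as the whole cause, of the splits of the libraries and of the way the adjusted values were made.

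A difference between the experiments, tested as an interaction, was seen in 988 genes. The log2 change with RB98# minus that after RBPMS knockdown was 4.75 for CDKN1C, 4.59 for JUN, 4.44 for PPP1R16B, 4.36 for FHL2 and 4.12 for DUSP8. It was -2.87 for RAC2, -2.81 for TBC1D10C, -2.70 for TRDC, -2.56 for CD33 and -2.51 for HSD17B10. The count was 92 to 1541 with a library left out and 4497 with the block, and JUN, FHL2, HSD17B10 and TBC1D10C lost their calls in some of the fits with a library left out. Each change was taken against its own experiment's controls, and the labels do not say whether both experiments were run side by side.

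The changes after the knockdown and with RB98# hardly correlated across genes (r = -0.08, exact permutation p = 0.5, and 0.278 with labels exchanged within the label sets). A shared effect that the label sets hide would give a clear positive r within a set, but the higher of both within-set values was -0.0373. Fold changes too noisy between libraries to correlate are argued against by the lower of both replicate correlations, 0.720, that of the RB98# replicates. The other, between the label sets of the knockdown, was 0.761. The RB98# replicates may not be separate cultures, so noise between cultures is left open there. That RB98# acts otherwise than loss of RBPMS may remain, and whether on other genes or in the opposite direction is open. A difference in dose or time is open and was not tested.

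Label sets 1 and 2 stood apart in both groups of the knockdown experiment. Library depth is argued against, since same-numbered deviations still correlated at 0.765 or more after thinning to the smallest total. Gene length and GC content could account for a share of 0.344 of the variance between the sets, which leaves their part open. As the whole cause they are argued against, since the correlation was still 0.710 or more after both trends were removed. No biological explanation was tested.

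The 10 splits of the 6 knockdown libraries into 3 and 3 are too few for a share under 0.05, and 1 split, the real one, gave as many as its 320 genes, with 0 as the highest of the others. With the replicate block there are 4 splits, also too few, and 1 split, the real one, gave 4549 genes, with 0 as the highest of the others.

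In the authors' adjusted values replicates 2 and 3 lay further apart than in the counts, with a median absolute log2 ratio of 0.352 against 0.0566 in shCtrl and 0.386 against 0.0630 in shRBPMS. ComBat-seq with the label set as batch gave gene deviations that correlated at 0.99983 with those of the adjusted values, against 0.818 with the replicate number as batch. A count adjustment of that kind for the label set is therefore a candidate explanation, while one for the replicate number is argued against.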

How the results depend on the processing

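Chosen after the results were seen were the tests on label set 2 alone, on label set 1 alone, on summed libraries with the label set as a covariate and on the authors' adjusted values. Where a result changed, the cause was not tested, except that a stricter threshold lowers a count by construction.

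The knockdown count of 320 genes was 1346 with DESeq2, 4549 with the replicate block, 1402 in a fit of all 10 libraries, 5810 with the label set as a covariate, 6830 in label set 2 only, 2681 with summed libraries and the label set, and 2331 with the authors' adjusted values. It was 6 at an adjusted p of 0.01, 0 in edgeR with replicates 2 and 3 summed (1086 at an unadjusted p under 0.05), and 0 to 322 with a library left out. With RB98# the count of 4659 was 352 in the fit of all 10 libraries, 543 with at least a 2-fold change, and 2731 to 5028 with a library left out. Where that leaves 1 library in a group, it is assumed to vary like the others. The difference, 988 genes, was 4497 with the block and 92 to 1541 with a library left out.

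Of the 9 gene lists called in the knockdown, a stricter count filter left a count of 4, fry 3 and an estimated correlation 0, and 9 to 13 were called with a library left out. The lymphoid, platelet, monocyte and histone lists lost the call with the label set as a covariate and in label set 2 only, and the first 2 with summed libraries and the label set. The 10 called with RB98# became 0 with an estimated correlation, while fry kept all 10. The estimate lay below the preset 0.01 for cholesterol synthesis (0.00717), ribosome biogenesis and MYC targets (-0.0227), the BCL2 family (-0.0275) and NF-kB genes (-0.0505). In the knockdown it did so for the USP1 list (-0.0946), platelet markers (-0.206) and lymphoid markers (-0.0363). A higher correlation is not what removed these calls, while the other called lists had estimates above 0.01. The list cytosolic ribosomal proteins under knockdown had an adjusted p between 0.000161 and 0.955 with a library left out, and changed direction without a call when shCtrl replicate 1 was left out (0.955).

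RBPMS after the knockdown passed with a log2 change of -1.97 (DESeq2), -1.79 (block), -1.95 (all 10 libraries), -1.79 (label set), -2.02 (summed with label set), -1.19 (set 2) and -1.52 (adjusted values), and lay between -2.23 and -1.30 with a library left out. FOXO1 passed with -1.52, -1.32, -1.50, -1.33, -1.52, -0.83 and -1.11 in the same order, and lay between -1.78 and -0.81. USP1 passed with -0.28 (block), -0.28 (label set) and -0.23 (set 2), and lay between -0.34 and -0.24. With RB98# FOXO1 lost its call in DESeq2 (-0.48) and in all 10 libraries (-0.48), and lay between -0.51 and -0.44, and USP1 between -0.16 and 0.0724. The correlation of both experiments was -0.129 in label set 1 and -0.105 to -0.0158 with a library left out.

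All 38 named knockdown calls held with the block, DESeq2, the label set, set 2 and the adjusted values, and 0 with replicates 2 and 3 summed. Of the 95 named RB98# results 82 held in DESeq2, 84 with library totals only and 30 in all 10 libraries. These counts include RBPMS, which was uncalled in every fit. Alternatives for the pseudocount and the low value filter of normalized values were not run, since counts were at hand. In the simulation the knockdown fit without the block found 3.23% of 2-fold changes.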

Other observations

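The values of library sets by gene list were chosen after the data were seen. The motif test was written before its result was seen.

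The label sets of the knockdown experiment were apart in the medians of whole gene groups. Mitochondrially encoded mRNAs were higher in set 1 than in set 2 by a median log2 ratio of 1.27 in shCtrl and 0.99 in shRBPMS. Cytosolic ribosomal proteins were lower in set 1 (-0.85 and -0.67), as were nuclear OXPHOS subunits (-0.64 and -0.57), AP-1 and immediate early genes (-1.03 and -0.64) and the BCL2 family (-0.51 and -0.47). Genes of G2 and mitosis were higher in set 1 (0.53 and 0.28). Cholesterol synthesis had -0.16 in shCtrl and 0.52 in shRBPMS. These are values of 1 library against 2, without a test.

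RBPMS binds RNA at tandem CAC motifs, so a hypothesis was that the density of these motifs in 3' UTRs marks the genes that changed after the knockdown. Over 9177 genes the Spearman rho of the blocked change with CAC density was 0.0520, against 0.0538 for ACC and 0.119 for CCA, each with a permutation p of 1e-05, the smallest that permutations can give. The size of rho for CAC minus the larger control was -0.0675, so CAC density followed the signed change no more closely than the controls did. A signed change cannot show a mark on genes that moved both ways, so the hypothesis is left open. With RB98# rho was -0.0314 for CAC, -0.0448 for ACC and -0.0710 for CCA. GC content accounted for a share of 0.0307 of the variance of the blocked change. Genes are not independent replicates.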
